A study of Mus musculus with 4 samples.

How the data were processed

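Each of the 4 arrays measured RNA from 1 liver sample, 2 from mice given GFP adenovirus and 2 from mice given lipin 1beta adenovirus, grouped by the sample titles. The deposited values are linear intensity values, 1 signal per probe set and array, made with MAS5 per the submitters' processing notes; the MAS5 version, the scaling target and the chip description are not given in the sources used here. The 2% trimmed mean was equal on all arrays, 1501, so the signals were taken as scaled by the authors' processing and used as deposited, with no further normalization. MAS5 subtracts mismatch probes and scales each array linearly, which leaves dim probe sets noisy and differences in signal range between arrays in place. No detection calls were used here, so signal over background is not known for a single probe set. Per the labels, lipin replicate 2 was polyA RNA and the other 3 samples total RNA, while the design text speaks of total RNA throughout; every sample is also labelled with Cy5, a dye not usual for this array type.

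Of 22690 probe sets, the 64 controls (AFFX) were left out. Signals under 119.5, the 20th percentile of all values, were raised to it, log2 was taken, and 13576 probe sets with a mean at or above the 40th percentile (a geometric mean signal of 373) were tested. Between 18.4% and 20.9% of an array's probe sets were raised. A linear model on group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), which pools the spread over probe sets, since 2 residual degrees of freedom are left, and gave 12.7 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Fold changes are on this floored log2 scale, so those of dim genes are understated. Errors of log2 differences are limma's standard errors.

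Gene names came from the platform annotation. Of the 22626 probe sets, 20380 had 1 symbol, 691 several and 1555 were not listed, and 20351 of the named ones matched the RefSeq gene table (GRCm38.p6) by Entrez identifier, used for names only. No coordinates are given because the values name no genome build. A gene (8493 tested) was represented by its tested probe set with the highest mean, and 2628 genes had several.

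The design, the tests, 31 gene lists from textbook knowledge and the rule for named genes were set before the data were examined. Named are all Lpin1 probe sets, Lpin2, Lpin3, Ppara and Ppargc1a, the up to 12 genes per direction that pass with the largest change, or where fewer pass, up to 6 per direction by smallest p, and up to 4 members by smallest p of each list described. Which 13 lists were described with members was chosen after their values were seen. Where genes outside this rule are named, they were chosen after their values were seen. The lists overlap in places, as Sdhd is both in oxidative phosphorylation and in the TCA cycle. Lists with at least 4 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in the same direction, were alternatives. Members were also counted with the p-values adjusted over the list alone. Some members of the lists are not reported here.

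Alternatives covered quantile normalization, median centring, other floors and filters, eBayes without a trend or robust, the replicate number as a block, leaving out each array in turn, thresholds of 0.1 and 0.01, a rule of 1.5 times without a test, leaving out probe sets that can match several transcripts, and the mean of a gene's probe sets. Camera with an estimated correlation and an array left out was added after the data were seen, and it has little power with 1 residual degree of freedom. With all arrays it has 2, and there it called 0 lists in every split of the arrays. A call lost in that version is therefore weak evidence about a list. With an array left out, the lone array of its group is assumed to vary like the others. Without either lipin replicate in turn, and with the replicate block, the prior degrees of freedom were infinite. There a gene's spread came from the intensity trend alone.

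The fit was tested on simulated data, 20 sets of 13576 probe sets with the spread of this comparison and 200 of them changed. It recovered 11.9% of 4-fold changes, 36.5% of 8-fold, 48.5% of 16-fold and 52.7% of 32-fold, with 4.80 false calls on average, so true changes of such sizes can stay below the threshold in this comparison. Rises and falls were simulated in equal number, and falls of dim probe sets were cut short at the floor. These shares therefore do not give the recovery of rises alone. With no change simulated, 628 to 735 probe sets had an unadjusted p under 0.05. For the mitochondrial fatty acid oxidation list, 200 simulations with no shift and uncorrelated members led camera to call it in 3.50%, and with the estimated correlation of 0.429 in 48.0%, against 1.00% with the correlation estimated. With the observed mean shift and that correlation, 96.0% were called at the preset correlation and 27.0% with it estimated. With that shift and uncorrelated members, the shares were 100% and 92.5%. These simulations tested this list alone, so a call in them had no adjustment over the lists. The shares are therefore not rates of the adjusted calls reported for the data.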

Results

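Gene expression was measured with Affymetrix Mouse Expression 430A arrays in liver from adult male C57BL6 mice. The mice had received an adenovirus that carried either green fluorescent protein (GFP), the control, or the beta form of mouse lipin 1, and were killed on day 6 after injection. Lipin 1, the product of Lpin1, is a phosphatidate phosphatase that makes diacylglycerol for lipid synthesis, and it also acts in the nucleus as a coactivator with PPAR alpha and PGC-1 alpha, regulators of fatty acid oxidation genes. The design holds 4 arrays, 2 per group, and a single comparison, which asks which liver transcripts differ between lipin overexpression and GFP. Nothing in the labels says that the arrays of a group came from separate animals, so the p-values of single probe sets measure the spread between these samples, which may be technical. Camera at the preset correlation compares a list's genes with the other genes. Its p-values rest mainly on the spread between genes, taken as nearly independent, and not on that between samples.

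Signals are in arbitrary units, and their trimmed mean was 1501 on every array. Median signals were 582 and 746 in GFP replicates 1 and 2, and 675 and 618 in lipin replicates 1 and 2. Across the 13576 probe sets tested, GFP replicate 2 stood apart, with a mean correlation of 0.731 with the other arrays against 0.781 to 0.793 for the rest. Its ratio of 3' to 5' beta-actin signal, a sign of RNA degradation, was 4.22, compared with 1.77 in GFP replicate 1, 2.85 in lipin replicate 1 and 2.86 in lipin replicate 2. The arrays did not group by treatment in these correlations. The GFP arrays correlated with each other at 0.737 and the arrays labelled lipin at 0.804. GFP replicate 1 correlated at 0.820 with lipin replicate 1 and at 0.824 with lipin replicate 2. The number of arrays limits the precision of every value below.

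Lpin1 itself was read by 2 probe sets, and only lipin replicate 2 exceeded both GFP arrays. The dimmer probe set had signals of 2730 and 1430 in the GFP arrays, 2261 in lipin replicate 1 and 6719 in lipin replicate 2, a log2 difference of 0.98 ± 0.53 (SE, n = 2 per group; limma adjusted p = 0.962). The brighter probe set read 7082 and 4632 in the GFP arrays, 3854 in lipin replicate 1 and 11087 in lipin replicate 2, a log2 difference of 0.19 ± 0.45 (limma adjusted p = 0.977). The latter difference was -0.57 without lipin replicate 2, -0.12 without GFP replicate 2 and 0.95 without lipin replicate 1, and that of the dimmer probe set ran from 0.19 without lipin replicate 2 to 1.77 without lipin replicate 1. Lipin replicate 1 therefore shows no Lpin1 signal above the control range, and every direction given for the arrays labelled lipin rests on those labels. Where the probes lie relative to the cDNA in the vector is not known here, and a probe set outside that part of the transcript checks nothing. The 3 tested probe sets of Lpin2, a related phosphatase, had log2 differences of 0.37 ± 0.37, 0.36 ± 0.63 and -0.82 ± 0.62, and the first of these was -0.080 without lipin replicate 2. The probe set of Lpin3 and all 5 probe sets of Ppargc1a, which encodes PGC-1 alpha, were too dim to test.

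Ppara, the nuclear receptor that drives hepatic fatty acid oxidation, was 5.0-fold higher in the arrays labelled lipin, and Igfbp2, a binding protein for insulin-like growth factors, was 10.4-fold higher. Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, was 5.74-fold higher. The lower genes with the smallest p included Apoa4, an apolipoprotein, at 2.55-fold lower, and Hmgcs1, the cytosolic HMG-CoA synthase of cholesterol synthesis, at 2.69-fold lower. None of these differences passed correction over all probe sets. On the log2 scale Igfbp2 stood at 2.40 without lipin replicate 2 and at 4.37 without lipin replicate 1, Ppara at 1.69 and 2.96, and Etfdh at 1.73 without GFP replicate 2. With limma, 0 probe sets were higher and 0 lower at an adjusted p under 0.05, and the lowest adjusted p was 0.660.

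At an unadjusted p under 0.05, 335 probe sets were higher and 261 lower, 596 in all, against 679 expected by chance. Of 8493 genes, 1469 had both arrays labelled lipin above both GFP arrays and 1362 had both below, together 33.3%, the share that chance gives for 2 against 2. A rule without a test, a change of at least 1.5 times on every pair of arrays, took 540 probe sets higher and 491 lower, and the same rule on the other splits of the arrays took 623 and 630, and 386 and 752. Without lipin replicate 1, 8 probe sets were higher and 6 lower at the limma threshold. The numbers were 1 and 1 without GFP replicate 2, 0 and 3 without lipin replicate 2, and 0 and 0 without GFP replicate 1. An exact test of a single gene with 2 arrays against 2 cannot go below p = 0.333, two-sided.

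Among the genes with the smallest p, 6 in each direction, both arrays labelled lipin lay on one side of both GFP arrays for each. Choosing genes by the p of this comparison makes such a separation likely, so it is no further support. Igfbp2 averaged 638 ± 345 in GFP and 7629 ± 6385 in lipin (SD, n = 2 each), a log2 difference of 3.38 ± 0.63 with a limma adjusted p of 0.660. Ppara read 1688 and 1695 in the GFP arrays, and 5452 and 13121 in lipin replicates 1 and 2, a log2 difference of 2.32 ± 0.44 (limma adjusted p = 0.660). Cyp2d13, a cytochrome P450, differed by 2.97 ± 0.63 on the log2 scale (adjusted p = 0.756), and its second probe set by 1.79. The first ran from 1.83 without GFP replicate 1 to 4.12 without GFP replicate 2. Etfdh differed by 2.52 ± 0.59 (adjusted p = 0.804) and Gjb1, a gap junction protein of hepatocytes, by 1.30 ± 0.32 (adjusted p = 0.962), with a second Gjb1 probe set at 0.44. Hsd17b6, a retinol and steroid dehydrogenase, gave 1.49 ± 0.34 on its brighter probe set and -1.44 ± 1.16 on the dimmer one. Without lipin replicate 1, Igfbp2, Ppara and Cyp2d13 stood at 4.37, 2.96 and 3.21 on the log2 scale. Without lipin replicate 2 they stood at 2.40, 1.69 and 2.74. In both fits a single array was left in the lipin group and a gene's spread came from the intensity trend alone. Tests of single genes in these fits therefore do not measure the spread of the gene itself.

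**Figure D1:**
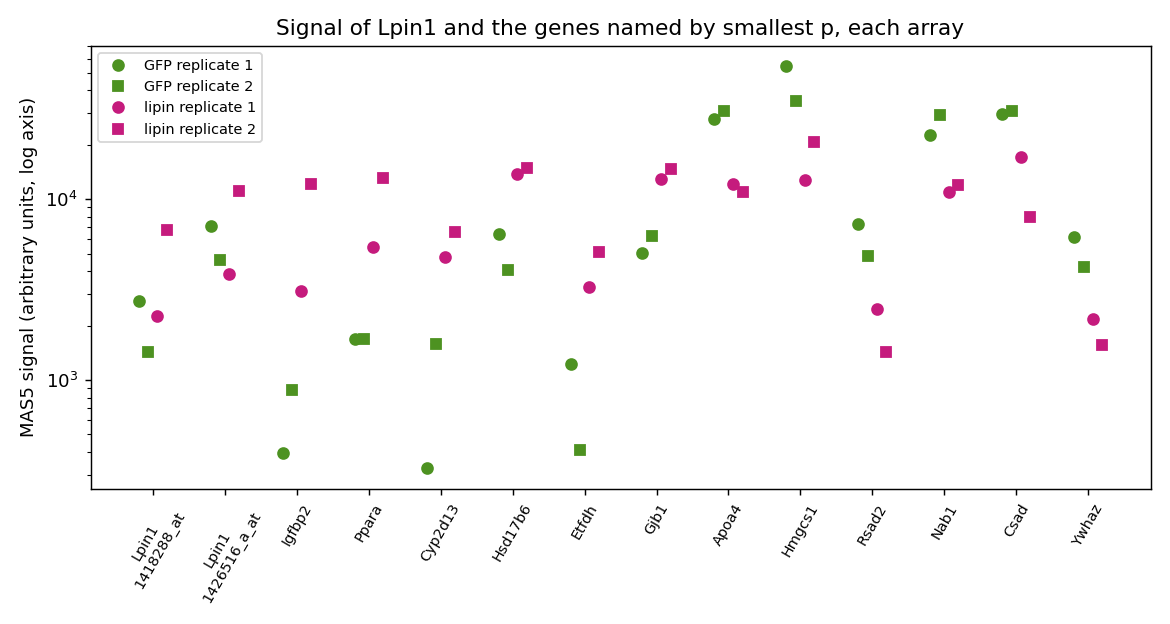
Signal of each array (arbitrary units, log axis) for both Lpin1 probe sets and the 6 genes per direction with the smallest p. Circles mark replicate 1 and squares replicate 2 of the GFP (green) and lipin (magenta) groups. Ppara lay at 1688 and 1695 in the GFP arrays and at 5452 and 13121 in the arrays labelled lipin, whereas Lpin1 exceeded both GFP arrays only in lipin replicate 2.

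On the lower side, Apoa4 averaged 29396 ± 2080 in GFP and 11530 ± 817 in lipin, a log2 difference of -1.35 ± 0.31 (limma adjusted p = 0.804), and its second probe set gave -1.60. Hmgcs1 had a log2 difference of -1.43 ± 0.36 (adjusted p = 0.962), with all 4 of its probe sets between -1.63 and -0.85. Csad, an enzyme of taurine synthesis, had -1.36 ± 0.37 (-0.81 without lipin replicate 2), and Nab1, a transcriptional corepressor, -1.17 ± 0.32, with a second Nab1 probe set at -0.70. Rsad2, the antiviral protein viperin, read -1.67 ± 0.43, but its 3 probe sets ran up to 0.01. Ywhaz, a 14-3-3 protein, read -1.47 ± 0.42, and its 6 probe sets ran up to 0.12. The limma adjusted p was 0.962 for Csad, Nab1, Rsad2 and Ywhaz.

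Mitochondrial fatty acid oxidation was the gene list that stood highest in the arrays labelled lipin. Its 19 tested members, of 20, had a median log2 difference of 0.54, or 1.45-fold, and 17 lay above 0. Limma's camera test against the other genes called the list higher (adjusted p = 5.74e-06). With the correlation of its members estimated, at 0.429, the camera adjusted p was 0.815 and the call was lost. That version rests on 2 residual degrees of freedom. Lists with estimated correlations of -0.05 and 0.04 went to 0.815 too, but their calls were near the threshold before (camera adjusted p = 0.0429 and 0.0252). In the simulations at a correlation of 0.429, not adjusted over the lists, the preset test called 48.0% without a shift and 96.0% with the observed shift. With the correlation estimated, 1.00% and 27.0% were called, so a loss was common with the shift too. The lost call therefore does not show that the correlation made it. In 11 members both arrays labelled lipin exceeded both GFP arrays and in 2 both lay below, where chance gives 3.17 each way. Besides Etfdh these included Acadvl, which starts the oxidation of long-chain acyl-CoA (log2 1.42 ± 0.38), Cpt2, which re-forms acyl-CoA inside mitochondria (1.5 ± 0.48), and Hadha of the trifunctional protein (1.00 ± 0.39). No member passed over all probe sets, and 3 were higher when adjusted over the list alone, namely Etfdh, Acadvl and Cpt2. The list's lowest array was GFP replicate 2, the array with the highest 3' to 5' actin ratio, at a median of -0.51 from the mean of all arrays against 0.04 in GFP replicate 1, 0.36 in lipin replicate 1 and 0.34 in lipin replicate 2. Without GFP replicate 2 the median was 0.40 and the camera adjusted p 0.0507, and Etfdh, Acadvl, Cpt2 and Hadha stood at 1.73, 0.92, 0.59 and 0.58. Cpt2 also has a dimmer probe set at 0.10. Camera also called the list higher with the arrays split against the labels, GFP replicate 1 and lipin replicate 2 against the others (median 0.29, adjusted p = 0.0392, and 0.965 with an estimated correlation). That split joins the arrays with the highest Lpin1 signals. It would also result if the labels of lipin replicate 1 and GFP replicate 1 had been exchanged, which is left open below. For replicate 1 against replicate 2 the median was 0.27 and the camera adjusted p 0.0818.

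Peroxisomal fatty acid oxidation showed a smaller shift. Its 15 tested members had a median log2 difference of 0.27 (1.20-fold), 11 lay above 0, and in 6 both arrays labelled lipin exceeded both GFP arrays against 2 with both below. The members with the smallest p were Ehhadh, the peroxisomal bifunctional enzyme (1.19 ± 0.42), Eci2, an enoyl-CoA isomerase (0.97 ± 0.34), Ech1, a dienoyl-CoA isomerase (0.97 ± 0.39), and Hsd17b4, the other bifunctional enzyme (0.82 ± 0.36). Without GFP replicate 2, Ech1 and Hsd17b4 stood at 0.43 and 0.41. Camera gave an adjusted p of 0.0429, and 0.815 with an estimated correlation; 0 members passed over all probe sets or when adjusted over the list alone. The call ended without GFP replicate 1 (median 0.15, adjusted p = 0.0838), without GFP replicate 2 (0.38 and 0.123), without lipin replicate 2 (0.14 and 0.224) and after quantile normalization (0.18 and 0.0990).

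Oxidative phosphorylation genes, the subunits of the respiratory chain and ATP synthase, had a median log2 difference of 0.21 (1.16-fold) over 60 tested members. In 26 of them both arrays labelled lipin exceeded both GFP arrays and in 6 both lay below, against 10 each way by chance. Ndufa6 of complex I read 0.96 ± 0.32, Sdhd of complex II 0.99 ± 0.39, Cox8a of complex IV 0.79 ± 0.35 and Atp5k of ATP synthase 0.85 ± 0.31. Second probe sets gave 1.08 for Sdhd and 1.40 for Cox8a, and the other Atp5k probe sets gave 0.69 and 0.11. Sdhd stood at 0.39 without GFP replicate 2 and Cox8a at 0.50 without lipin replicate 1. Camera called the list higher (adjusted p = 0.0252), and an estimated correlation gave an adjusted p of 0.815, with 0 members past the threshold over all probe sets or adjusted over the list alone. The call was lost without GFP replicate 1 (median 0.16, adjusted p = 0.125), without lipin replicate 2 (0.11 and 0.368) and after quantile normalization (0.14 and 0.129).

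**Figure D2:**
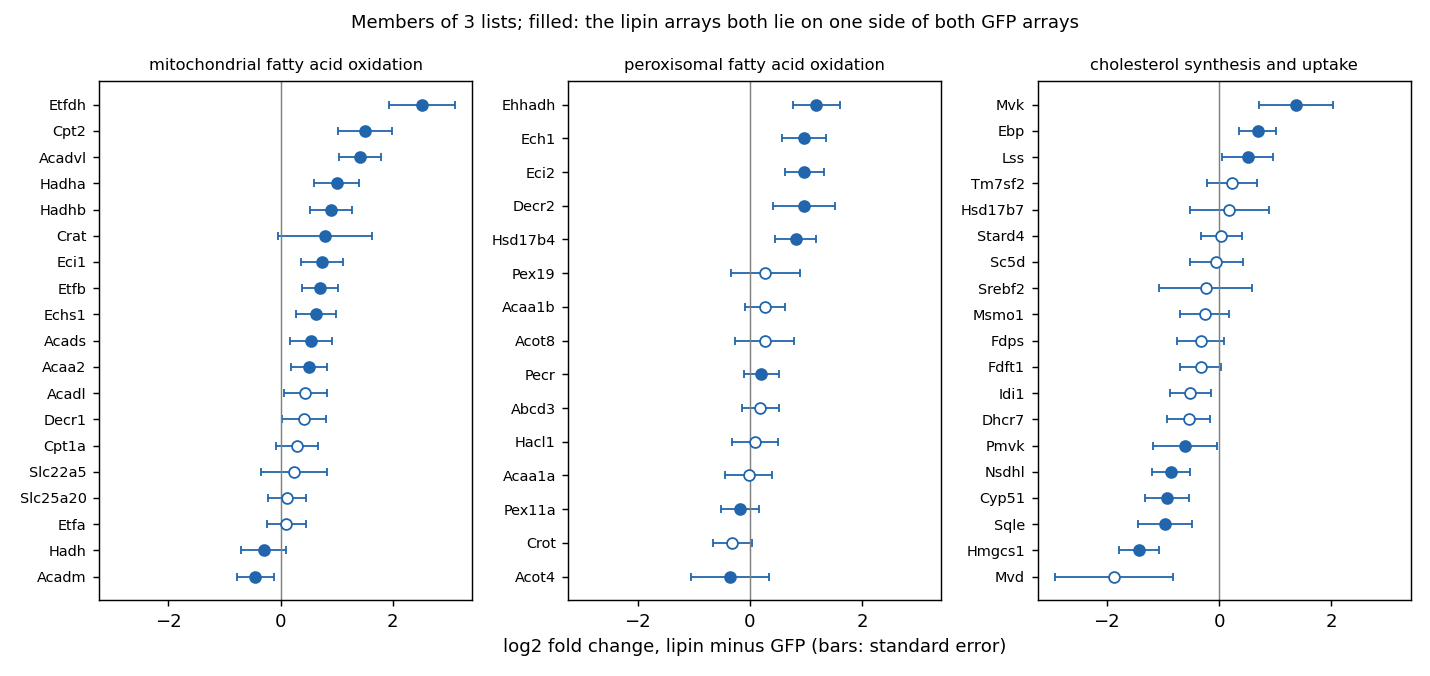
Log2 fold change of each tested member of 3 gene lists, lipin minus GFP, with bars for the standard error and filled points where both arrays labelled lipin lay on one side of both GFP arrays. In mitochondrial fatty acid oxidation 17 of 19 points lie above 0, in peroxisomal fatty acid oxidation 11 of 15, and in cholesterol synthesis and uptake 6 of 19.

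Of the regulators around PGC-1 and PPAR, Ppara stood alone. It was the single member of 18 that was higher when adjusted over the list alone. Hnf4a, a hepatocyte nuclear receptor, gave 0.95 ± 0.37 on its brightest probe set, and its 4 probe sets ran from -0.12 to 0.95. Without GFP replicate 2 the brightest stood at 0.37. Esrra, an orphan receptor partnered with PGC-1 alpha, gave 1.04 ± 0.76, or 0.56 without lipin replicate 1. Rxrb gave 1.66 ± 1.07, a value that was -0.0041 without GFP replicate 2, where its signal lay under the floor. The list's median was 0.06 (camera adjusted p = 0.253), and -0.11 without GFP replicate 2. Other targets of PPAR alpha did not move together, with a median of -0.08 over 15 members and an adjusted p of 0.984, although the mean and the camera direction were positive. Fabp1, the fatty acid binding protein of liver, read 1.01 ± 0.48, the fatty acid transporter Slc27a2 0.64 ± 0.35 and Vnn1 1.70 ± 1.09, whereas the acyl-CoA thioesterase Acot1 read -0.79 ± 0.49. Vnn1 and Slc27a2 stood at 0.12 and 0.34 without GFP replicate 1, and Acot1 at -0.34 without lipin replicate 2. No member passed, over all probe sets or adjusted over the list alone. The median was 0.12 without GFP replicate 1 and 0.07 without lipin replicate 1. Pdk4, Fgf21, Cidec and Acot2 were too dim to test.

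Cholesterol synthesis genes lay on the other side, and Hmgcs1 had the smallest p among them. The 19 tested members had a median log2 difference of -0.32, 13 lay below 0, and the list did not pass (camera adjusted p = 0.0760, and 0.821 with an estimated correlation). Nsdhl (-0.85 ± 0.34) and Cyp51 (-0.93 ± 0.39), which remove the methyl groups of lanosterol, came next by p, and the mevalonate kinase Mvk read 1.38 ± 0.66, or 0.55 without GFP replicate 1. Nsdhl and Cyp51 stood at -0.55 and -0.54 without lipin replicate 1, and a dimmer Cyp51 probe set gave -0.34 with all arrays. Hmgcs1 alone was lower when adjusted over the list alone. The lipin arrays differed here, with medians of -0.50 from the mean of all arrays in lipin replicate 1 and 0.11 in lipin replicate 2. Without lipin replicate 2 the median was -0.80 and the list was called lower (adjusted p = 0.000155, and 0.977 with an estimated correlation), and without lipin replicate 1 it was 0.12.

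Fatty acid synthesis genes split in both directions. Srebf1, the transcription factor of lipogenesis, read 1.20 ± 0.35, the desaturase Fads2 1.08 ± 0.34 and Thrsp, a lipogenic protein, 0.95 ± 0.37, with the second probe sets of Fads2 and Thrsp at 1.20 and 1.53. Elovl5, a fatty acid elongase, read -0.86 ± 0.36, and Srebf1 stood at 0.78 without GFP replicate 2. The median of the 16 members was 0.20 and the mean -0.02, and 0 members and the list itself did not pass (adjusted p = 0.253). The median was -0.13 without GFP replicate 2, and without GFP replicate 1 it was 0.51 and called higher (adjusted p = 0.0443, and 0.986 with an estimated correlation).

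In glycerolipid and phospholipid synthesis, the pathway of lipin itself, 22 tested members had a median of 0.07 (adjusted p = 0.253), and -0.07 without GFP replicate 2. Pcyt2, of phosphatidylethanolamine synthesis, read 1.17 ± 0.49 and Dgat2, which makes triacylglycerol, 0.77 ± 0.34, with a second Dgat2 probe set at 0.30. Pcyt2 stood at 0.31 without GFP replicate 2 and Dgat2 at 0.44 without GFP replicate 1. Chkb, a choline kinase, read 1.62 ± 1.09 and Lpcat3, a lysophospholipid acyltransferase, 0.80 ± 0.59, and their values were -0.0072 and -0.39 without GFP replicate 2. No member passed. Lipoprotein genes had a median of 0.23 over 22 members (adjusted p = 0.253), and 0.29 without GFP replicate 2, with an adjusted p of 0.0313, and of 0.857 with an estimated correlation. It was 0.087 without GFP replicate 1 (adjusted p = 0.861) and 0.098 without lipin replicate 2 (0.926). Apoa4 was lower when adjusted over the list alone. Apoc1 read 1.16 ± 0.42 (0.65 without GFP replicate 1), Lcat, which esterifies cholesterol in plasma, 0.73 ± 0.32, and Mttp, which loads lipid onto apolipoprotein B, -0.66 ± 0.32, with a second probe set at -0.03. The median of gluconeogenesis genes was 0.14 over 13 members (adjusted p = 0.482), with 0.070 without GFP replicate 2 and 0.22 without GFP replicate 1. There Igfbp1, which insulin represses, read -1.69 ± 0.63, whereas the glucose 6-phosphate transporter Slc37a4 read 0.85 ± 0.33, pyruvate carboxylase Pcx 0.77 ± 0.34 and tyrosine aminotransferase Tat 0.76 ± 0.39 (0.18 without lipin replicate 2), and 0 members passed.

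Interferon response and cell cycle genes differed more by replicate number than by group, with medians of 0.89 and 1.06 for replicate 1 minus replicate 2 (adjusted p = 0.385 for each with an estimated correlation). For lipin against GFP, interferon response genes had a median of -0.14 over 38 members (adjusted p = 0.192). Besides Rsad2, the GTPase Ifi47 read -0.99 ± 0.43 and the RNA sensor Ifih1 -0.94 ± 0.46, while Ifi35 read 2.15 ± 0.94. Ifi47 and Ifih1 stood at -0.29 and -0.56 without GFP replicate 1, and Ifi35 at 0.57 without GFP replicate 2. The list's median was 0.27 without GFP replicate 1 and 0.11 without lipin replicate 2, but it was called lower without GFP replicate 2 (-0.76, adjusted p = 7.38e-10) and without lipin replicate 1 (-0.45, adjusted p = 0.000868). Both calls were lost with an estimated correlation (adjusted p = 0.857 and 0.754). Cell cycle genes had a median of -0.46 over 30 members (adjusted p = 0.0760). The replication licensing factors Mcm7 and Mcm2 read -1.31 ± 0.49 and -1.28 ± 0.64, Cdc20, an activator of mitotic exit, -1.15 ± 0.59 and thymidine kinase Tk1 1.57 ± 0.77. The dimmer probe sets of Mcm7 gave -0.07, 0.04 and 1.07, that of Mcm2 0.05 and that of Cdc20 -0.34. Cdc20 stood at -0.12 without lipin replicate 2 and at -2.18 without lipin replicate 1. Mcm7 ran from -2.01 without GFP replicate 2 to -0.62 without GFP replicate 1, and Mcm2 from -2.07 to -0.49 without the same arrays. The median was 0.38 without lipin replicate 2, and the list was called lower without lipin replicate 1 (-1.31, adjusted p = 2.09e-08) and without GFP replicate 2 (-0.98, adjusted p = 2.06e-05). An estimated correlation gave adjusted p of 0.754 and 0.857 for these. Markers of T and NK cells had a median of -0.65 over 12 members, 10 of them below 0 (adjusted p = 0.192), and of -0.37 without lipin replicate 1 and -1.08 without GFP replicate 1. Gzma, a granzyme, read -1.86 ± 1.21, the T cell kinase Zap70 -0.58 ± 0.42, the chemokine receptor Cxcr6 -1.63 ± 1.20 and Cd5 1.77 ± 1.34. Gzma stood at -0.75 without lipin replicate 2, Cxcr6 at -0.36 without lipin replicate 1 and Cd5 at 0.78 without GFP replicate 1. In these 3 lists 0 members passed, over all probe sets or adjusted over the list alone.

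The other 18 lists did not pass either, and 0 of their members were past the threshold or adjusted over the list alone. Among metabolic lists, median log2 differences were 0.21 for ketone body metabolism (camera adjusted p = 0.907), 0.08 for the TCA cycle (0.291), 0.17 for glycolysis (0.562), 0.15 for bile acid synthesis and transport (0.253), 0.15 for drug metabolism (0.229) and 0.21 for amino acid catabolism and the urea cycle (0.219). The TCA cycle median was -0.05 after quantile normalization, and ran from 0.016 without lipin replicate 1 to 0.22 without GFP replicate 1. That of glycolysis ran from 0.024 without lipin replicate 1 to 0.41 without lipin replicate 2. Among stress and rhythm lists, medians were 0.15 for the acute phase response (0.984), 0.12 for endoplasmic reticulum stress (0.253), -0.53 for p53 targets (0.215) and 0.36 for the circadian clock and its output (0.117). Hepatocyte markers had a median of 0.14 (0.215), macrophage, Kupffer cell and neutrophil markers -0.09 (0.997), B and plasma cell markers -0.45 (0.299, and a median of -0.89 without lipin replicate 2), endothelial markers 0.09 (0.994) and stellate cell and matrix markers -0.35 (0.215). Cholangiocyte and progenitor markers stood at 0.33 (0.984), red blood cell markers at -0.81 (0.822) and pancreatic acinar markers at -0.49 (0.50). Median and mean differed in sign for ketone bodies, glycolysis, the acute phase response and the macrophage, endothelial and cholangiocyte markers, and camera's direction opposed the median for the acute phase and cholangiocyte lists. With an array left out, camera called some of these lists at the preset correlation, and none with an estimated correlation, where the adjusted p was 0.986 without GFP replicate 1, 0.857 without GFP replicate 2 and 0.754 without lipin replicate 1 for each list named next. Without GFP replicate 2 the calls were higher for bile acids (median 0.41, adjusted p = 0.0196), drug metabolism (0.34 and 0.0313), amino acid catabolism (0.43 and 0.00286) and hepatocyte markers (0.54 and 0.00286), and lower for macrophage markers (-0.72 and 0.00286) and p53 targets (-0.75 and 0.00502). Without lipin replicate 1 they were higher for bile acids (0.48 and 0.00125), amino acid catabolism (0.41 and 0.00125) and the circadian clock (0.85 and 0.0107), and lower for p53 targets (-0.75 and 0.00425). Macrophage markers were called higher without GFP replicate 1 (0.39 and 0.0443).

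**Figure D3:**
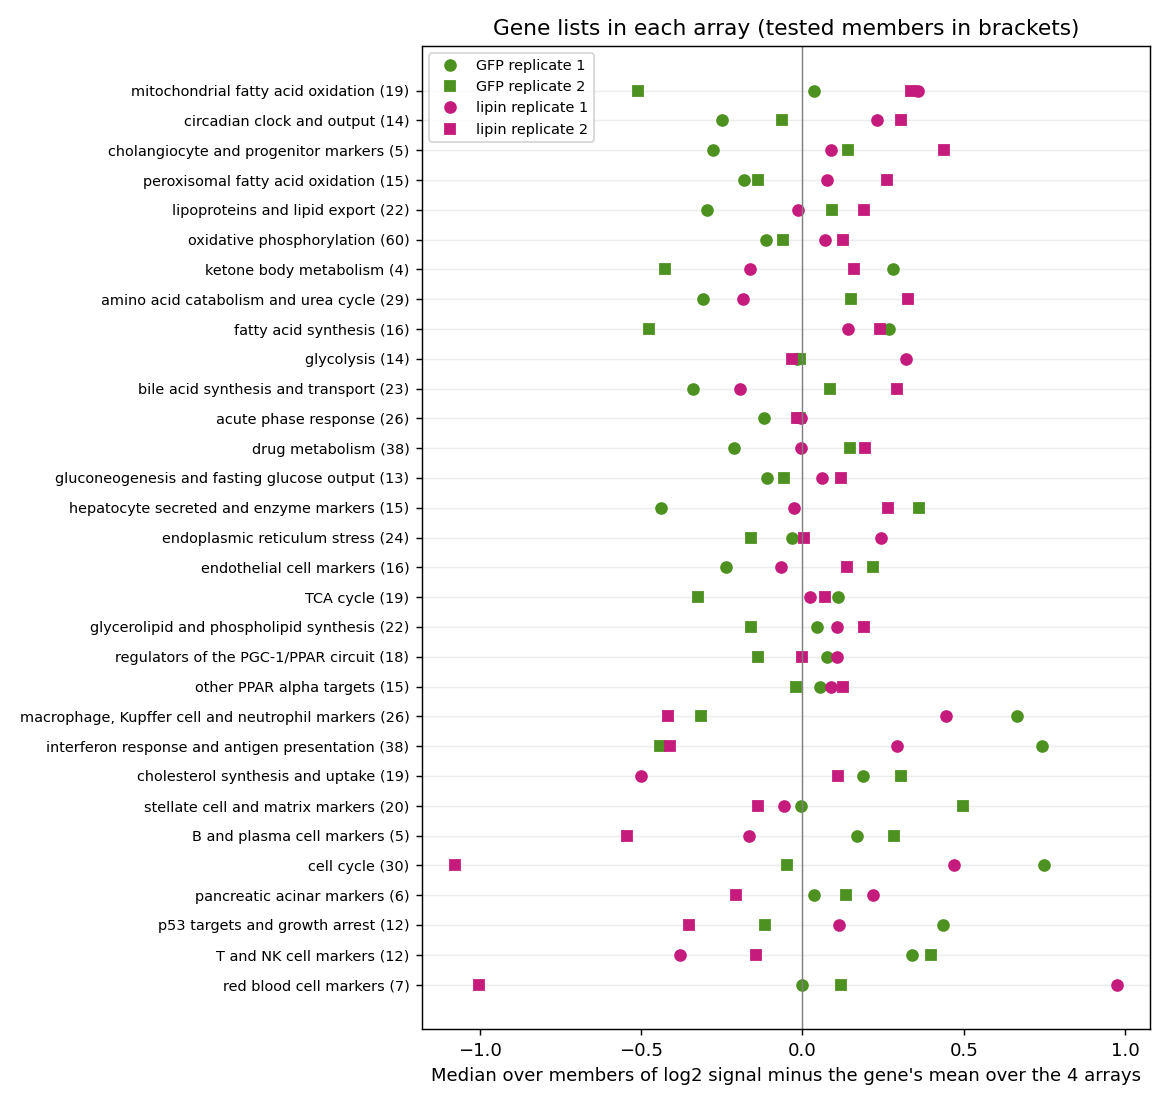
Median over the tested members of each list (their number in brackets) of the log2 signal minus the gene's mean over the 4 arrays, for each array. In mitochondrial fatty acid oxidation GFP replicate 2 lies at -0.51 and the arrays labelled lipin at 0.36 and 0.34, whereas in the interferon and cell cycle lists the replicate 1 arrays (circles) of both groups lie above the replicate 2 arrays (squares).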

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

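The alternatives below were set before the data were examined, except camera with an estimated correlation and an array left out, which was chosen after seeing the data. Of 60 named genes, 534 values under other settings and 239 with an array left out were recomputed; 4 of these genes, and the brighter Lpin1 probe set, which is not counted among them, changed direction, each only with an array left out, and 0 genes lost a call, since none had passed. Under quantile normalization, median centring, other floors and filters, no trend, robust eBayes and without ambiguous probe sets, 0 probe sets passed in either direction, as with thresholds of 0.1 and 0.01. The cause of the changes listed here was not tested except where fewer arrays or a rule without a test make the setting different by construction.

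For lists, quantile normalization left 1 called higher, with medians of 0.18 for peroxisomal fatty acid oxidation, 0.14 for oxidative phosphorylation and -0.053 for the TCA cycle. Leaving out the intensity trend also left 1, with the medians of these called lists unaltered at 0.27 and 0.21 but their calls lost. Median centring put the peroxisomal list at 0.30 and no filter at 0.24, without a call. No filter put the macrophage list at 0.11, and a floor at the 40th percentile put cholangiocyte markers at -0.12 and red blood cell markers at 0.042. A filter at the 60th percentile called the circadian clock higher (0.67, adjusted p = 0.0444). With the mean of a gene's probe sets, 1 list, cholesterol synthesis, was called lower (-0.41, adjusted p = 0.0290). Camera with an estimated correlation and fry each called 0 lists, with the medians of mitochondrial fatty acid oxidation (0.54), peroxisomal fatty acid oxidation (0.27) and oxidative phosphorylation (0.21) the same and adjusted p of 0.815 and 0.831. The rule of 1.5 times took 540 probe sets higher and 491 lower.

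Over all probe sets, same-numbered arrays of the groups deviated from their group means with a correlation of only 0.028. Interferon, macrophage and cell cycle genes nevertheless shifted the same way in both groups, as described below. With 2 pairs the numbers are not taken to pair the samples. With the replicate number as a block, 34 probe sets were higher, 18 lower, and 2 lists were called lower, cholesterol synthesis (-0.32, adjusted p = 0.0188) and the cell cycle (-0.46, 0.0119), with the circadian clock called higher (0.36, 0.0331) and the 3 lists called without the block still called. Ppara had an adjusted p of 8.67e-06, and 14 named genes passed in this setting on the probe set that represents them. In simulations with no change this block fit made calls in 13 of 20 sets, 6.65 on average and up to 36.

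Leaving out each array in turn gave 0 to 8 probe sets higher and 0 to 6 lower, and 1 to 6 lists higher and 0 to 4 lower, or 0 lists either way with an estimated correlation as well (adjusted p of 0.754 or more, at 1 residual degree of freedom). The ranges of log2 differences were -0.57 to 0.95 for the brighter Lpin1 probe set, -0.080 to 0.82 for Lpin2, -0.0041 to 3.31 for Rxrb, -0.0072 to 3.23 for Chkb and -0.39 to 1.99 for Lpcat3. Called lists ranged from 0.40 to 0.79 for mitochondrial fatty acid oxidation, 0.14 to 0.45 for peroxisomal fatty acid oxidation and 0.11 to 0.24 for oxidative phosphorylation. The lists whose medians changed sign ranged as follows in lipid and sugar metabolism: other PPAR alpha targets -0.14 to 0.12, ketone bodies -0.17 to 0.34, PGC-1 and PPAR regulators -0.11 to 0.13, fatty acid synthesis -0.13 to 0.51, cholesterol synthesis -0.80 to 0.12 and glycerolipid synthesis -0.074 to 0.20. In liver function they were bile acids -0.13 to 0.48, drug metabolism -0.0053 to 0.34, amino acid catabolism -0.12 to 0.43, acute phase -0.042 to 0.085 and hepatocyte markers -0.24 to 0.54. In immune and other cells they were interferon -0.76 to 0.27, macrophages -0.72 to 0.39, stellate cells -0.49 to 0.073, endothelium -0.10 to 0.24, cholangiocytes -0.84 to 0.62, red blood cells -1.41 to 0.57 and pancreatic acini -0.94 to 0.12. The rest were cell cycle -1.31 to 0.38, p53 targets -0.75 to 0.036, endoplasmic reticulum stress -0.015 to 0.29 and the circadian clock -0.16 to 0.85. Lists not called with all 4 arrays that kept their sign were lipoproteins 0.087 to 0.31, gluconeogenesis 0.070 to 0.22, the TCA cycle 0.016 to 0.22, glycolysis 0.024 to 0.41, T and NK cells -1.08 to -0.37 and B and plasma cells -0.89 to -0.39.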

Other observations

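The explanations weighed here, the values held against them and the bounds on those values were chosen after the results were seen, although quantile normalization, leaving out an array and the estimated correlation were among the alternatives set before, and the genes named here were chosen after their values were seen. The pattern below was noticed among 3 ways of splitting the arrays and 31 lists. In both groups the arrays numbered replicate 1 had higher signals of interferon, macrophage and cell cycle genes than those numbered replicate 2, and the labels do not say whether these come from separate animals. The median log2 difference, replicate 1 minus replicate 2, was 0.89 for 38 interferon response genes, 1.03 for 26 macrophage, Kupffer cell and neutrophil markers and 1.06 for 30 cell cycle genes. Within groups these were 0.89, 0.89 and 0.94 in GFP and 0.52, 0.79 and 1.47 in lipin, and the GFP values involve GFP replicate 2, the array that stood apart with an actin ratio of 4.22. These are 1.85-, 2.05- and 2.09-fold, with camera adjusted p of 5.28e-13, 5.03e-08 and 1.62e-11, and 0.385 for each with an estimated correlation. Of these genes, 27 of 38, 17 of 26 and 21 of 30 were higher in replicate 1 of both groups. Cxcl9, a chemokine induced by interferon gamma, was 4.25-fold higher, the guanylate binding protein Gbp2 5.38-fold, and Psmb9, of the immunoproteasome, 12.5-fold, though the last was near the floor in GFP replicate 2. The lysozyme Lyz1 was 4.75-fold higher and Cd5l, a macrophage protein, 2.32-fold, whereas the Kupffer cell receptors Vsig4 and Clec4f were at 0.369 and 0.334 times the replicate 2 level. The replication genes Rrm2 and Pcna were 5.02-fold and 3.69-fold higher, and Birc5 and Cdk1 8.34-fold and 7.85-fold, with lipin replicate 2 under the floor for both.

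The same division of the arrays put some lists of hepatocyte genes, and endothelial markers, lower in replicate 1, with medians of -0.53 for amino acid catabolism and the urea cycle, -0.45 for bile acid synthesis and transport, -0.49 for hepatocyte markers, -0.34 for cholesterol synthesis and -0.50 for endothelial markers. Their camera adjusted p were 2.30e-07, 7.01e-06, 0.00181, 0.0160 and 0.0264, and with an estimated correlation 0.385, 0.590, 0.598, 0.598 and 0.598. Other metabolic lists lay on the higher side without passing, with medians of 0.38 for the TCA cycle (adjusted p = 0.119), 0.31 for glycolysis (0.304) and 0.27 for mitochondrial fatty acid oxidation (0.0818). T and NK cell markers had a median of -0.20 (adjusted p = 0.752). Over all probe sets, limma found 783 at an unadjusted p under 0.05 for replicate 1 against replicate 2, compared with 596 for lipin against GFP, and 1 probe set passed, which has no symbol in the table used (37102 and 3073 in the GFP arrays, 19365 and 3745 in those labelled lipin).

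If the arrays come from separate animals, a different strength of the response to the adenovirus is a hypothesis for this pattern, and no test for it was possible because uninjected livers are not analysed here. A lower share of hepatocytes would raise the markers of the other cell types together, if these kept their proportions. Endothelial and stellate markers instead had a median of -0.36 against 1.03 for macrophage markers. The permutation p of this difference was 1e-05, the smallest that 100000 resamples can give. It treats genes as independent and measures their spread, not that between samples, for a list picked after its values were seen. Red blood cell markers lay at 1.08 over 7 members (camera adjusted p = 0.199). Other changes in cell make-up stay open, since hepatocyte markers also lay lower, at -0.49. Uneven scaling would shrink under quantile normalization, but the lowest of the 3 medians was still 0.84. That the numbers mark separate batches of mice or of RNA stays open, since the labels do not say, and same-numbered arrays deviated from their group means with a correlation of only 0.028 across all probe sets. A batch that acts on a limited set of genes may leave such a value.

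Higher mitochondrial fatty acid oxidation transcripts in the arrays labelled lipin are the pattern nearest to the design, and an effect of lipin 1 on these genes remains a hypothesis. Uneven scaling as the whole cause is argued against by quantile normalization, after which the median was 0.53 and the call held. Members that vary together between arrays could give such a call, since their estimated correlation was 0.43. That correlation was 0.79 without lipin replicate 1 and 0.60 without lipin replicate 2, but -0.03 without GFP replicate 1 and without GFP replicate 2. It thus rested mainly on the gap between the GFP arrays, and is not separate from the low values of GFP replicate 2. The call was lost with the correlation estimated. Lists with estimated correlations of -0.05 and 0.04 lost their calls too, but these were near the threshold before (camera adjusted p = 0.0429 and 0.0252). In simulations of the observed shift, not adjusted over the lists, that version called 92.5% with uncorrelated members and 27.0% at a correlation of 0.429. A loss can thus come with a true shift. With 2 residual degrees of freedom in that version, the loss does not show that the correlation made the call. The low values of GFP replicate 2, the array with the highest 3' to 5' actin ratio, may account for part of the shift, which was 0.40 without that array, with an adjusted p of 0.0507. The other splits of the arrays gave medians of 0.27 and 0.29, the latter called by camera (adjusted p = 0.0392, and 0.965 with an estimated correlation), and 3 splits are too few for a test of chance. The latter split would also result if the labels of lipin replicate 1 and GFP replicate 1 had been exchanged. It is therefore not a clean control.

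Lpin1 in the array labelled lipin replicate 1 lay within or below the range of the GFP arrays. If the labels of lipin replicate 1 and GFP replicate 1 had been exchanged, both Lpin1 probe sets would separate the groups, but that was seen before the test, and the exchanged labels gave 397 probe sets at an unadjusted p under 0.05 against 596 for the labels as given. The count was to speak for an exchange above 1.5 times that of either other split and against it below 0.5 times 596. It met neither bound, both chosen after the counts were seen, and a bound of 596 divided by 1.5, not used, would lie at 397 itself, so an exchange stays open. Probe sets outside the part of the transcript that the vector carries may also miss the transgene, and the dimmer Lpin1 probe set was 1.77 higher on the log2 scale without lipin replicate 1, a difference that did not pass, and weak delivery of the virus in that sample was not tested.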
